A study of Mus musculus with 4 samples.

How the data were processed

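RNA was sequenced from 4 samples of mouse CD4+ T cells, 2 WT and 2 Batf3-/-, each stimulated for 72 h under TH9 conditions with TL1A (the treatment tag of the labels spells this cytokine TLA1). Libraries were made from polyadenylated RNA with a stranded kit, per the labels' protocols. The deposited table gives RSEM expected counts per gene, which are estimates that divide reads shared by several genes and need not be whole. The authors used STAR 2.5.0 and RSEM 1.2.25 on build GRCm38, per the submitters' processing notes. The annotation release and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes and close paralogs are reported as uncertain. The table holds 25509 genes with identifiers and symbols as well as spike-in control entries, which were 0 in all libraries and were left out.

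Samples were assigned to genotype by the genotype label and numbered by the replicate number in their titles. Expected counts were rounded to whole numbers before the count models, and values printed as counts are as deposited. Total counts per library ranged from 15624874 (Batf3-/- replicate 2) to 31098059 (Batf3-/- replicate 1). The floor for a gene at 0 was 3 counts, which correspond to 0.129, 0.109, 0.0944 and 0.194 CPM in WT 1, WT 2, Batf3-/- 1 and Batf3-/- 2. Floors cover counting error only, since PCR copies are not independent molecules. The 10 most abundant genes took 7.15% to 7.61% of counts per library. Replicates were compared before averaging: the chi-square per degree of freedom between replicates was 63.0 in WT (12739 genes) and 22.8 in Batf3-/- (12728 genes), far above sampling noise, so no 2 libraries were treated as 1.

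Differential expression was tested in R 4.3.3 with edgeR 4.0.16: filterByExpr with default settings (minimum count 10, minimum total count 15), TMM normalization (factors 0.982 to 1.02), robust dispersion estimates, glmQLFit with legacy=FALSE and glmQLFTest, two-sided, with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 0.171. Levels are TMM-normalized CPM, given as mean ± SD of 2 libraries, and log2 fold changes are Batf3-/- minus WT with their standard errors. Per-replicate log2 ratios use log2 CPM with a prior count of 0.5.

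In total 38 gene lists were fixed for helper T cell subsets, transcription factor families, signalling, metabolism, cell cycle, stress, sex-linked and mitochondrial genes and for markers of other cell types. The 30 lists with at least 5 tested members were tested with camera in limma 3.58.1 (two-sided, inter-gene correlation 0.01, Benjamini-Hochberg adjustment over the lists), and again with an estimated correlation and with fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes. Counts per list were also adjusted over the list alone.

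Genes were named by a rule: Batf3; the panel Il9, Il10, Foxp3, Ifng, Il17a, Il4, Il5, Il13, Spi1, Irf4, Batf, Gata3, Tbx21 and Tnfrsf25 among others, passing or not; up to 8 genes per direction with the largest change among those past the threshold with a mean log2 CPM of at least 2 and non-overlapping libraries, passing over predicted genes, pseudogenes, ribosomal protein genes and receptor segments; and from each list up to 4 members past the threshold or, with none, at most 2 with the smallest p as values. This left Batf3 with 3 other lower and 5 higher genes from the test. Lyplal1, Fcgr2b, Hist1h2ai, Gm20683, Gm2174, E130218I03Rik, Jund, Socs3 and, in the closing section, further neighbours of Batf3 were named after their values were seen. The groups, tests, gene lists, naming rule and the first set of other settings were chosen before the data were examined.

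These other settings were DESeq2's size factors, upper-quartile scaling, no filter, a filter of at least 1 CPM in 2 libraries, DESeq2 1.42.0 (Wald test), limma-voom, legacy=TRUE, leaving out each library in turn, the replicate number as a block, and a 2-fold threshold. A correction for GC content (offsets from each library's trend on the GC content of the longest transcript of each gene) and a test that left out genes within 25 Mb of Batf3 were added after seeing the data. Gene positions, biotypes and transcript GC came from GENCODE M21 on GRCm38, matched on gene identifiers without version; 12105 of 12135 tested genes matched, and coordinates are 1-based. Enrichment near Batf3 was tested with Fisher's exact test and with 100000 random draws of tested genes after merging called genes within 1 Mb into 1 locus.

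The pipeline was tested on simulated counts drawn from the means and library sizes of the Batf3-/- against WT comparison, with 200 genes changed by known folds. Over 11992 genes edgeR recovered 52% of 2-fold and 89% of 4-fold changes with 4 false calls among 152; DESeq2 recovered 56% and 88% with 10 false calls among 167 over 12135 genes, and voom 51% and 90% with 3 false calls among 152 over 11992 genes. Camera recovered a simulated list of shifted genes, and 1 of 100 lists of unchanged genes had a p under 0.05. The simulated genes were drawn independently of each other. Their spread followed the trend of dispersion on level, with no GC trend and no outlying library. Recovery in the data may therefore differ. In the data the estimated correlation was 0.19 among AP-1 and ATF genes and 0.607 among mitochondrially encoded genes. The simulated share therefore does not give camera's error rate for such lists.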

Results

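Gene expression was measured by RNA sequencing in mouse T cells cultured under conditions that promote the TH9 state, a helper T cell state defined by secretion of interleukin 9. Naive CD4+ T cells sorted from spleen (CD25-negative and CD44-low among the sort gates) were stimulated for 72 h with antibodies to CD3 and CD28 in the presence of TGF-beta, IL-4 and TL1A, the TNF-family ligand of the receptor encoded by Tnfrsf25. There were 2 libraries from wild-type (WT) cells and 2 from Batf3-/- cells, made by polyadenylated RNA selection with a stranded kit. Estimated counts summed to 23754946 and 27285811 in WT replicates 1 and 2. They summed to 31098059 and 15624874 in Batf3-/- replicates 1 and 2. Between 14104 and 14937 of the 25509 listed genes had a count in a library, and 12135 genes had enough counts to be tested. The labels do not say that the replicates came from separate mice or cultures, so the p-values measure only the spread between these 4 samples.

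The replicates differed in sex-linked RNA in both genotypes. Xist, transcribed from the inactive X chromosome of female cells, stood at 0.214 CPM (counts-per-million units) in WT replicate 1 and 0.0944 in Batf3-/- replicate 1, against 166 in WT replicate 2 and 144 in Batf3-/- replicate 2. The Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d were present in every library, with summed levels of 344 and 146 CPM in WT replicates 1 and 2 and of 243 and 182 CPM in Batf3-/- replicates 1 and 2. Replicates 1 and 2 of a genotype were therefore not repeat libraries of the same cells. Because this split runs along the replicate numbers, values within each replicate number are given beside the pooled ones for several results. WT replicate 1 also stood slightly apart over all tested genes: its log2 CPM correlated with the other libraries at 0.971 to 0.976, against 0.981 to 0.982 among the other 3.

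The comparison of Batf3-/- with WT cells asked which transcripts depend on BATF3, a basic leucine zipper transcription factor of the AP-1 superfamily, in TH9 cultures. Batf3 RNA was nearly lost, and outside that gene few transcripts passed the test. In Batf3-/- cells 10 genes were higher and 6, Batf3 included, were lower. With the replicate number as a block these counts were 81 and 31, in a fit that treated the spread of most genes as known. In simulated counts without a GC trend or an outlying library, edgeR recovered 52% of 2-fold changes. The surface receptor gene Slamf7 fell 11.3-fold and the Fc receptor gene Fcgr3 rose 61.9-fold from a level near the detection limit. Socs1, which encodes an inhibitor of cytokine receptor signalling, rose 2.13-fold but did not pass after a correction for GC content. Of the 16 genes, 8 lie within 25 Mb of Batf3 on chromosome 1. Il9 itself and the lineage regulators Irf4, Batf and Gata3 did not pass the test.

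Batf3 (ENSMUSG00000026630.9, GRCm38 chromosome 1, 191097847 to 191108945, protein coding) had 1439 and 1661 counts in the WT libraries and 17 and 8 in the Batf3-/- libraries. Its level was 61.1 ± 0.809 CPM in WT and 0.526 ± 0.0126 CPM in Batf3-/- cells (mean ± SD, n = 2 each), so that 0.861% of the WT level remained. The log2 fold change was -6.84 (SE 0.297, adjusted p = 3.80e-11, edgeR quasi-likelihood test). All 4 libraries carried the Batf3 level that their genotype label implies. The labels do not say which exons the allele lacks, so the remaining reads could not be placed inside or outside the deleted part.

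**Figure D1:**
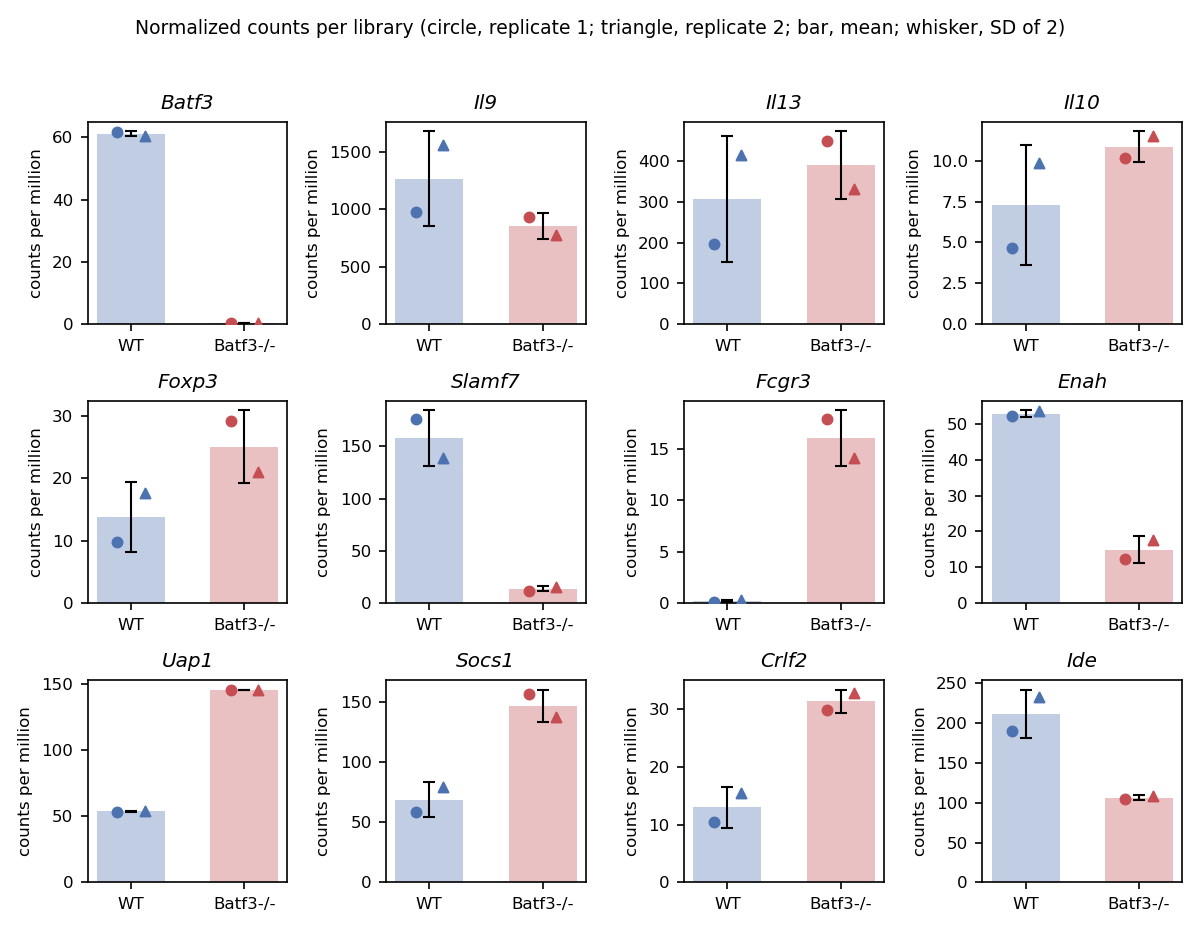
TMM-normalized CPM of 12 genes in each library, with 1 panel per gene and its own vertical axis from 0. Circles mark replicate 1 and triangles replicate 2, bars give the mean and whiskers the SD of 2 libraries; Batf3, Slamf7, Enah and Ide lie lower and Fcgr3, Uap1, Socs1 and Crlf2 higher in both Batf3-/- libraries, while Il13 overlaps between genotypes.

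Among the genes that fell, Slamf7 (chromosome 1, 171632403 to 171653035), a SLAM-family receptor of lymphocytes, went from 158 ± 26.5 CPM in WT to 14.1 ± 2.73 CPM in Batf3-/- cells (log2 fold change -3.49, SE 0.223, adjusted p = 1.81e-08). Enah (chromosome 1, 181896384 to 182019990), an actin regulator, went from 52.8 ± 0.924 to 14.9 ± 3.73 CPM (log2 fold change -1.83, SE 0.221, adjusted p = 3.23e-04). Ide (chromosome 19, 37268743 to 37337852), the insulin-degrading enzyme, fell 1.99-fold from 212 ± 30.2 to 106 ± 3.13 CPM (log2 fold change -0.99, SE 0.191, adjusted p = 0.0415). The other 2 lower genes were the predicted gene Gm2174 and the locus E130218I03Rik, at log2 fold changes of -1.17 and -2.53. Both carried fractional estimated counts, which arise where reads are divided between loci, and their values are uncertain. All of these adjusted p-values come from edgeR's quasi-likelihood test over 12135 genes with 2 libraries per genotype. For all 16 genes both Batf3-/- libraries lay on the same side of both WT libraries. Such separation held for 33.8% of all tested genes, and chance alone gives 33.3%.

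Among the genes that rose, Fcgr3 (chromosome 1, 171051174 to 171064935) encodes a low-affinity receptor for immunoglobulin G. It had 4 and 9 counts in the WT libraries and 570.24 and 218.30 in the Batf3-/- libraries. These are 0.25 ± 0.111 against 16.0 ± 2.72 CPM (log2 fold change 5.95, SE 0.401, adjusted p = 3.20e-08, edgeR). Uap1 (chromosome 1, 170141938 to 170174957), an enzyme of UDP-N-acetylglucosamine synthesis, rose from 53.8 ± 0.306 to 146 ± 0.249 CPM (log2 fold change 1.44, SE 0.185, adjusted p = 6.61e-04). Socs1 (chromosome 16, 10782240 to 10785536) rose from 68.7 ± 14.8 to 147 ± 13.6 CPM (log2 fold change 1.09, SE 0.200, adjusted p = 0.0296). Crlf2 (chromosome 5, 109554709 to 109558993), a subunit of the receptor for the epithelial cytokine TSLP, rose from 13.0 ± 3.61 to 31.4 ± 2.06 CPM (log2 fold change 1.27, SE 0.231, adjusted p = 0.0296). Within replicates 1 and 2 the log2 ratios were 1.42 and 0.79 for Socs1 and 1.51 and 1.08 for Crlf2, and for Scand1 they were 2.24 and 1.18. Scand1 (chromosome 2, 156311847 to 156312704), a small SCAN-domain protein gene, rose from 8.15 ± 3.58 to 25.4 ± 1.71 CPM (log2 fold change 1.63, SE 0.269, adjusted p = 0.0168), with fractional counts in both genotypes. Adjusted p-values for these genes are from the same edgeR test.

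The remaining higher genes were expressed at low levels, and those named here were named only after their values were seen. Lyplal1, a lysophospholipase-like gene, went from 4 and 2 counts to 93 and 20 (log2 fold change 4.20, SE 0.689). Fcgr2b, which neighbours Fcgr3 and encodes the inhibitory Fc receptor, had 0 counts in both WT libraries and 33.76 and 21.70 in the Batf3-/- libraries. It was at least 10.4-fold higher against a floor of 3 counts per WT library. In each Batf3-/- library the fractional counts of Fcgr3 and Fcgr2b added up to a whole number of reads (604 and 240, within 0.02), so reads shared by these paralogs were divided between them and the Fcgr2b level is uncertain. Hist1h2ai, a member of a multicopy histone family with the same uncertainty, had 0 counts in both WT libraries and 30.02 and 20.12 in the Batf3-/- libraries, at least 9.44-fold higher. The predicted gene Gm20683 was at a log2 fold change of 1.94 with fractional counts. Without Batf3-/- replicate 1, Lyplal1 was among the genes that no longer passed in edgeR, as were Gm20683, Socs1, Crlf2 and Ide. Their log2 fold changes were then 3.39 for Lyplal1, 1.94 for Gm20683, 0.99 for Socs1, 1.33 for Crlf2 and -0.97 for Ide.

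**Figure D2:**
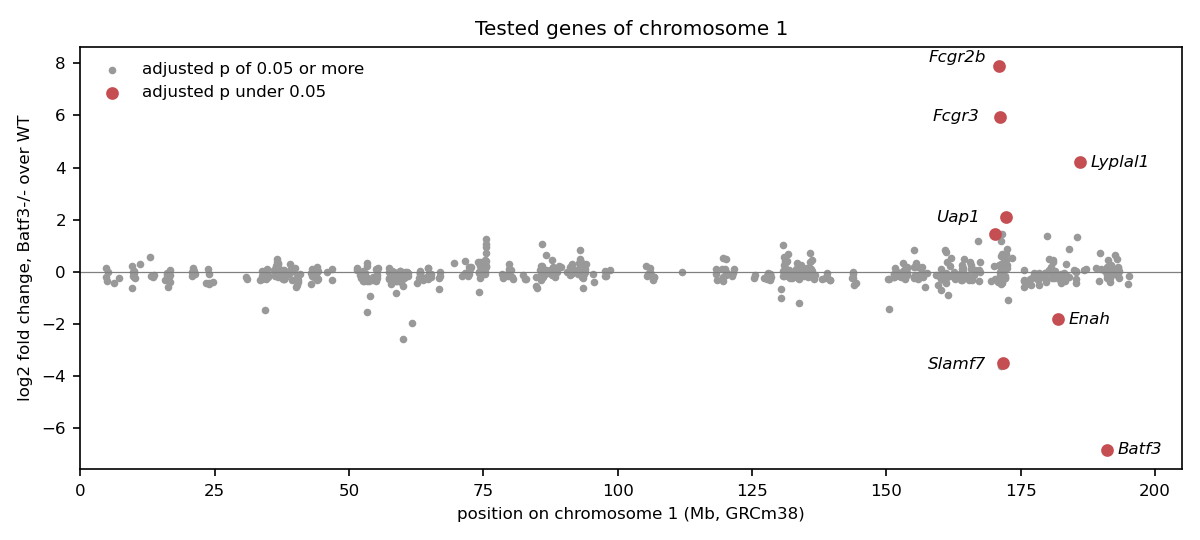
Log2 fold change, Batf3-/- over WT, of each tested gene of chromosome 1 against its GRCm38 position in megabases. Red points, most with their symbols, are the 8 genes with an adjusted p under 0.05, which lie in the stretch from Uap1 to Batf3; the Fcgr2b point is a fitted value that depends on the prior count, because both WT libraries were at 0.

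Slamf7, Fcgr3, Fcgr2b, Uap1, Enah and Lyplal1 all lie on chromosome 1 between 4.98 and 20.9 Mb from Batf3. Of the 146 tested genes within 25 Mb of Batf3, which is 1.21% of those with a position, 8 passed the test with Batf3 included. Without Batf3 itself the share was 4.83%, against 0.0669% elsewhere in the genome. The stretch from 170 to 180 Mb, which holds the Fc receptor and SLAM receptor clusters, had 64 tested genes, of which 5 passed the test and 20 had an unadjusted p under 0.05. Among the 24 tested genes within 2 Mb of Batf3, 0 passed and 1 had an unadjusted p under 0.05 in edgeR.

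Over all 12135 genes, edgeR's quasi-likelihood test gave 583 genes with an unadjusted p under 0.05, 413 of them higher and 170 lower in Batf3-/- cells, where 607 would be expected by chance. The counts of 10 higher and 6 lower genes became 38 and 24 without WT replicate 1, 301 and 252 without WT replicate 2, and 23 and 15 without Batf3-/- replicate 2. Without Batf3-/- replicate 1 they were 11 and 7, of which 5 and 3 were among the genes called with all libraries. In edgeR with all genes within 25 Mb of Batf3 left out, 0 genes passed and 557 had an unadjusted p under 0.05, with Socs1 and Crlf2 at an adjusted p of 0.0702; this changes the adjustment, not the fold changes. After a correction for GC content the log2 fold changes were 0.82 for Socs1 (from 1.09), 1.03 for Scand1 (from 1.63), -0.87 for Ide (from -0.99) and 0.75 for Crlf2 (from 1.27). Their adjusted p-values in edgeR were then 0.113, 0.113, 0.119 and 0.375. Hist1h2ai (adjusted p = 0.125) and Gm20683 (adjusted p = 0.113) missed the threshold too. None of the higher genes called outside the 25 Mb window before the correction kept its call. The median transcript GC of those higher genes was 65.6%, against 49.8% for all tested genes. The lower genes Gm2174 and E130218I03Rik kept their calls. Both checks were added after the data were seen.

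Il9, the cytokine gene that defines these cultures, was among the abundant transcripts in both genotypes and did not pass the test. Its level was 978 and 1559 CPM in WT replicates 1 and 2 and 932 and 773 CPM in Batf3-/- replicates 1 and 2. The Batf3-/- mean was 67.2% of WT (log2 fold change -0.57, SE 0.228, unadjusted p = 0.0211, adjusted p = 0.898, edgeR quasi-likelihood test). The log2 ratio was -0.07 within replicate 1 and -1.01 within replicate 2. Without WT replicate 1 the log2 fold change was -0.88, and without WT replicate 2 it was -0.20. In each case 1 WT library was left, so the spread between WT libraries was not counted.

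Other cytokine genes of the culture showed no difference past the threshold in edgeR. Il13 stood at 306 ± 154 CPM in WT and 389 ± 83.1 CPM in Batf3-/- cells, Il5 at 70.3 ± 2.68 and 61.3 ± 13.6 CPM, and Il4 at 13.7 ± 5.06 and 9.91 ± 0.759 CPM. Il10, an anti-inflammatory cytokine gene, stood at 7.28 ± 3.68 and 10.8 ± 0.950 CPM (log2 fold change 0.56, SE 0.304, adjusted p = 0.958). Il22, a cytokine of TH17 and TH22 cells, had a log2 fold change of 2.07 (SE 0.428, adjusted p = 0.0733) at 1.03 ± 0.607 and 4.27 ± 1.66 CPM, and passed when adjusted over the list alone, for the 12 tested TH17 genes and for the 30 tested cytokine genes. That cytokine list as a whole had 17 of 30 members positive (median 0.05, camera adjusted p = 0.507). Ifng, at 3 and 10 counts in WT and 1 and 0 in Batf3-/- libraries, and Il17a, at 2 and 1 against 6 and 0 counts, lay too low to be tested. Without WT replicate 2 the log2 fold changes of Il13, Il10, Il4 and Il22 were 0.98, 1.21, -0.80 and 2.88. Without WT replicate 1 they were -0.10, 0.12, -0.04 and 1.59, with 1 WT library left in each case. For Il22 the log2 fold change was 2.37 without Batf3-/- replicate 2. Within replicates 1 and 2 the log2 ratios were 1.18 and -0.33 for Il13, 1.12 and 0.22 for Il10, -0.73 and -0.12 for Il4 and 3.14 and 1.08 for Il22.

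Of the lineage regulators, Foxp3, the transcription factor of regulatory T cells, had the smallest p: 13.8 ± 5.58 CPM in WT and 25.1 ± 5.77 CPM in Batf3-/- cells (log2 fold change 0.87, SE 0.269, unadjusted p = 0.00493, adjusted p = 0.593 in edgeR). Its log2 ratio was 1.57 within replicate 1 and 0.25 within replicate 2, and its log2 fold change was 1.36 without WT replicate 2. With the replicate number as a block, Foxp3 passed in edgeR (log2 fold change 0.91, adjusted p = 0.00542), as did Il22 (adjusted p = 7.6e-05). That fit treated the spread of most genes as known (median prior degrees of freedom infinite, against 16.8 unblocked). Its p-values for such genes made no allowance for having 1 residual degree of freedom. The TH9 regulators Irf4 and Batf stood at log2 fold changes of -0.08 (SE 0.205) and 0.10 (SE 0.188), and Spi1, encoding PU.1, had 1 count in WT replicate 2 and 0 in the other libraries. Gata3, the TH2 regulator, had a log2 fold change of 0.29 (SE 0.196) and Tbx21, the TH1 regulator, of -0.55 (SE 0.567), with Tbx21 at 2.01 and 8.09 CPM in the WT libraries. The log2 fold change of Tbx21 was -1.22 without WT replicate 1 and 0.79 without WT replicate 2. Its log2 ratio was 0.75 within replicate 1 and -1.16 within replicate 2. Tnfrsf25, the TL1A receptor gene, stood at 32.3 ± 2.78 and 41.8 ± 0.299 CPM (log2 fold change 0.37, SE 0.197).

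Helper T cell gene lists fixed in advance were compared as groups with camera, limma's competitive gene set test. Of 18 tested TH9 genes, 8 had positive and 10 negative log2 fold changes (median -0.04, adjusted p = 0.585), with none passing over all genes or adjusted over the list alone; Erg, an ETS factor, stood at -0.87 (adjusted p = 0.708). Regulatory T cell genes had 15 of 21 positive (median 0.15, adjusted p = 0.059), and Itgae, an integrin subunit, stood at 0.74 beside Foxp3. TH2 genes had 10 of 17 positive (median 0.15, adjusted p = 0.585), with the chemokine receptor Ccr8 at 0.48 and the hypoxia-inducible factor Epas1 at 0.42. TH1 genes had 8 of 14 positive (median 0.08, adjusted p = 0.928), with the cytokine receptor subunits Il12rb1 at 0.41 and Il18r1 at -0.41. TH17 genes had 4 of 12 positive (adjusted p = 0.680); their median was -0.04 while their mean, raised by Il22, was 0.13. Follicular helper genes had 7 of 14 positive (adjusted p = 0.741), with Cd200 at -0.36 and Btla at -0.40. Without WT replicate 1 the TH9 list had a median of -0.19, and without WT replicate 2 a median of 0.13, with 1 WT library left in each case.

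Among signalling and transcription factor lists, 3 were shifted upwards in Batf3-/- cells by camera with an inter-gene correlation of 0.01. With an estimated correlation none of the 3 passed (adjusted p = 0.905 each). That test rests on 2 residual degrees of freedom and had little room to pass. The AP-1 and ATF family had 14 of 19 members positive (median 0.21, adjusted p = 0.00229), and Junb, Atf5 and Jund, at log2 fold changes of 0.93, 0.88 and 0.75, passed when adjusted over the list alone but not over all genes (adjusted p = 0.252, 0.263 and 0.534 in edgeR). Within replicates 1 and 2 the log2 ratios of Junb were 1.44 and 0.50, those of Jund 1.29 and 0.30 and those of Atf5 0.94 and 0.83, and the list medians were 0.41 and 0.14. Early genes of T cell receptor signalling had 19 of 20 members positive (median 0.23, 0.48 within replicate 1 and 0.05 within replicate 2, adjusted p = 0.00229), with none passing alone; the orphan nuclear receptor Nr4a1 stood at 0.46 and the RNA-binding protein gene Zfp36 at 0.40. The IL-4, IL-2 and STAT response list had 14 of 18 positive (median 0.08, adjusted p = 0.0314), with Socs1 the 1 member past the threshold and Socs3 at 0.65.

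Mitochondrially encoded genes were shifted downwards, with 11 of 13 negative (median -0.31, camera adjusted p = 2.08e-04), and did not pass with an estimated correlation (adjusted p = 0.905). Among them mt-Atp8, at -0.87, passed when adjusted over the list alone, and mt-Nd6 stood at -0.51. The mitochondrial share of counts was 1.92% and 1.65% in WT and 1.53% and 1.31% in Batf3-/- libraries. With an estimated correlation 0 of the 30 lists tested passed. Fry also called 0 lists (adjusted p = 0.902 for each of the 4). With either method 0 lists had an unadjusted p under 0.05. Camera with an estimated correlation rests on the 2 residual degrees of freedom of these libraries. The smallest unadjusted p over the lists was 0.143 by that test and 0.0567 by fry. Either test had little room to pass with 4 libraries, so a miss says little for or against the shifts. Without WT replicate 1 the adjusted camera p was 0.397 for AP-1 and ATF genes, 0.586 for early T cell receptor genes and 0.964 for the IL-4, IL-2 and STAT list, whose median was then -0.04, while mitochondrial genes stood at 0.00266. Without Batf3-/- replicate 2 the mitochondrial list had a median of -0.08 (adjusted p = 0.297) and the IL-4, IL-2 and STAT list an adjusted p of 0.135. Without Batf3-/- replicate 1 that list and the early T cell receptor list had adjusted p-values of 0.0513 and 0.0524. Log2 fold changes also ran with GC content: across 12105 genes, which are not independent replicates, Spearman's rho with transcript GC was 0.578 (0.556 within replicate 1, 0.261 within replicate 2). After the GC correction camera called 0 lists, with 7 at an unadjusted p under 0.05, and the medians of the early T cell receptor and mitochondrial lists were 0.10 and -0.07.

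**Figure D3:**
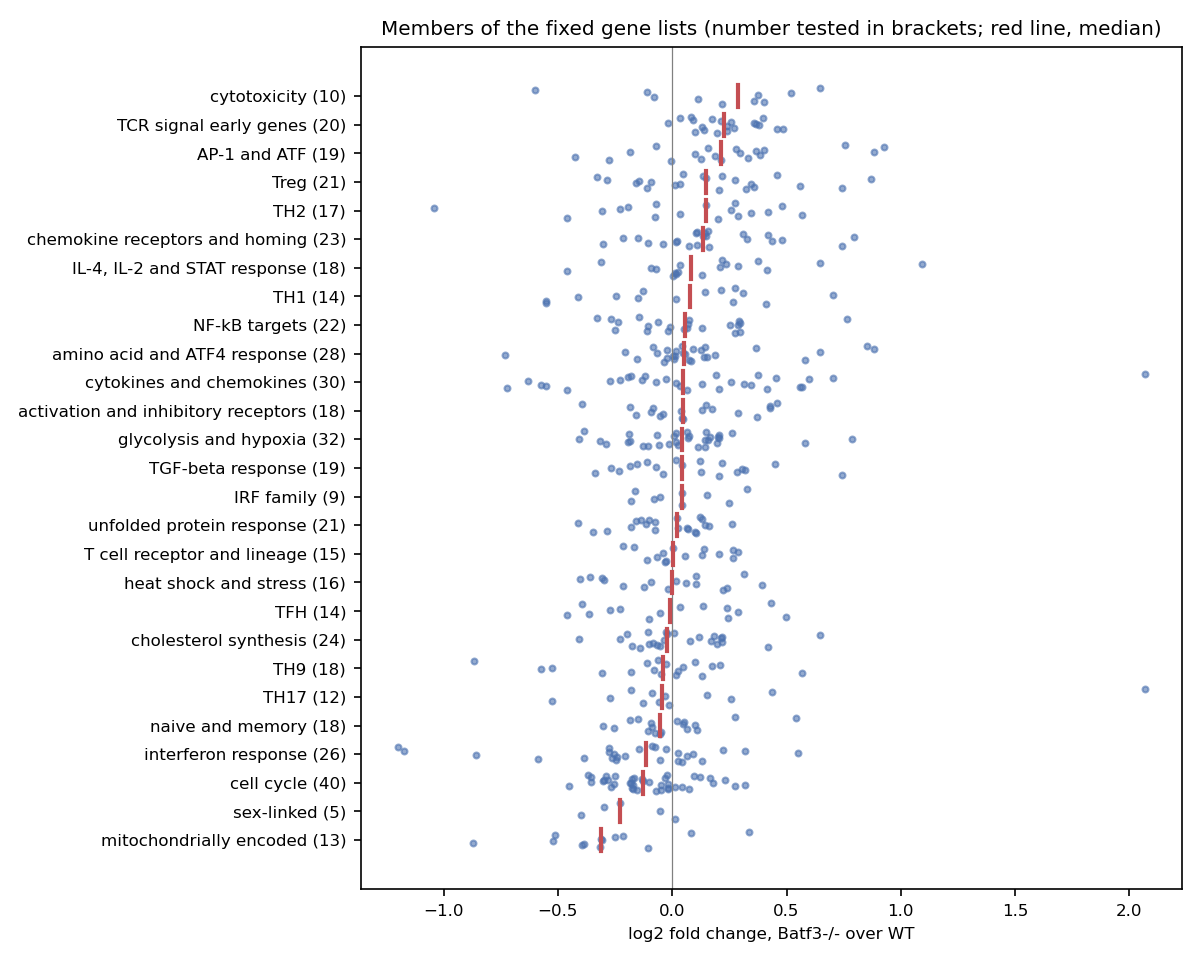
Log2 fold change, Batf3-/- over WT, of each tested member of 27 gene lists fixed in advance, with the number tested in brackets and a red line at the list median. Medians run from -0.31 for mitochondrially encoded genes to 0.29 for cytotoxicity genes, and the medians of the AP-1 and early T cell receptor lists lie at 0.21 and 0.23.

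Other lists did not pass by camera. Cell cycle genes had 30 of 40 members negative (median -0.13, adjusted p = 0.059), with the survivin gene Birc5 at -0.45 and the kinesin Cenpe at -0.37. Interferon response genes had 17 of 26 negative (median -0.11, adjusted p = 0.142). The RNA sensor gene Ifih1 stood at -0.59, and Oasl1, with only 5 to 37 counts per library, at -1.18. Chemokine receptor and homing genes had 18 of 23 positive (median 0.14, adjusted p = 0.142). Amino acid and ATF4 response genes had 20 of 28 positive (median 0.05, adjusted p = 0.106), and Atf5 and Cebpb (0.85) passed adjusted over the list alone. NF-kB targets had 12 of 22 positive (median 0.06, adjusted p = 0.585), and Bcl3, an NF-kB cofactor, passed adjusted over the list alone at 0.76. Activation and inhibitory receptors had 11 of 18 positive (median 0.05), with Lag3 at 0.43, and TGF-beta response genes had 11 of 19 positive (median 0.04), with Smurf2 at -0.34. Glycolysis and hypoxia genes had 20 of 32 positive (median 0.04), with the lactate transporter Slc16a3 at 0.79 and Ddit4 at 0.58. Leaving out 1 library, so that 1 genotype had no spread of its own, brought some lists past the threshold of camera. Cell cycle genes passed without WT replicate 1 (adjusted p = 0.0123) and without Batf3-/- replicate 1 (adjusted p = 0.00113), and regulatory T cell genes without WT replicate 2 (adjusted p = 0.016). Amino acid and ATF4 response genes passed without WT replicate 2 (adjusted p = 0.0145) and Batf3-/- replicate 2 (adjusted p = 0.00861), as did cytokine genes (adjusted p = 0.0087 and 0.03), and interferon response genes without Batf3-/- replicate 2 (adjusted p = 0.0165).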

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

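The tests with the GC correction and without genes within 25 Mb of Batf3 were chosen only after the results were seen. Batf3 kept its call in every setting that tested it (log2 fold change -7.20 to -6.80), and so did Slamf7, Enah, Fcgr3, Fcgr2b and Uap1. Against 10 higher and 6 lower genes, DESeq2's Wald test called 20 and 8, all 16 among them, and the GC correction 7 and 5, with 5 and 5 shared. Leaving out each library gave 11 to 301 higher genes, 7 to 252 lower genes and 3 to 8 lists against 4; with 1 library left in a genotype, that library is assumed to vary like the others. The highest counts came without WT replicate 2, where WT replicate 1 stood alone; Foxp3, Il13 and Junb then passed, and Il9, Erg and Tbx21 passed without WT replicate 1. A replicate block called 81 higher and 31 lower genes, among them all 16, with Foxp3 (adjusted p = 0.00542), Il22, Junb, mt-Atp8, Slc16a3, Bcl3, Atf5, Cebpb and Socs3 now past the threshold and Il9 not (adjusted p = 0.267). The titles give same-numbered libraries a shared code, and sex-linked RNA follows it, but the labels do not say what it marks. Whether the libraries are paired therefore stays open. Their deviations correlated at 0.105, and the blocked fit leaves 1 residual degree of freedom. The block lowered the common biological coefficient of variation from 0.171 to 0.147. The median prior degrees of freedom rose from 16.8 to infinity. For most genes the blocked p-values therefore made no allowance for the 1 residual degree of freedom. By replicate number 864 genes had an unadjusted p under 0.05 in edgeR, against 583 by genotype. Leaving out genes within 25 Mb of Batf3 gave 0 higher and 0 lower genes (557 at an unadjusted p under 0.05 in edgeR); the unadjusted p-values of the other genes were the same. The lists called fell to 0 with the GC correction, with an estimated correlation and with fry. Fry and the estimated-correlation test had little room to pass with so few libraries. The median of the sex-linked list was 0.53 without WT replicate 1 (adjusted p = 0.00543) and -0.48 without WT replicate 2 (adjusted p = 0.00424), against -0.23. Beyond what is stated, the cause of these differences was not tested. The other scalings and filters gave 8 to 10 higher and 6 to 7 lower genes, voom 10 and 5, the legacy fit 8 and 6. Scalings moved the median of all genes by at most 0.03. Depth limits genes such as Ifng and Il17a, which lay under the filter. In simulation, without a GC trend or an outlying library, 2-fold changes were recovered in 52% of cases.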

Other observations

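The tests of position near Batf3, shared Fc receptor reads, myeloid genes, sex-linked RNA, WT replicate 1, GC content and other splits of the libraries were chosen only after the results were seen.

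Most markers of other cell types lay under 1 CPM in both genotypes. All 9 neutrophil genes, 9 of 10 mast cell and basophil genes, 9 of 10 natural killer and innate lymphoid genes, 10 of 11 erythroid and platelet genes, 3 of 4 plasma cell genes and the 1 listed gamma delta T cell gene, Sox13, lay under 1 CPM in every library. So did 13 of 17 myeloid, 10 of 15 B cell, 7 of 11 dendritic cell and 7 of 11 stromal genes and 1 of 2 CD8 T cell genes. The exceptions at the highest levels were H2-Ab1, a class II antigen gene, at up to 166 CPM, the invariant chain gene Cd74 at up to 82.2 CPM, the protease inhibitor gene Cst3 at up to 53.3 CPM and the protease gene Ctss at up to 40.2 CPM. Lower exceptions, present in all libraries, included Pecam1 of the stromal list at up to 24.9 CPM and H2-DMb2 of the dendritic list at up to 16.3 CPM. Ebf1 and Cd79b of the B cell list reached 17.2 and 13.1 CPM. Apart from Fcgr3, no marker passed over all genes in edgeR. Sdc1, a plasma cell marker, stood at a log2 fold change of 0.80, Cd8b1 at -0.24, the natural killer receptor Klra7 at -0.77, and Kit at -0.16. The myeloid list had a median of 0.02 and a mean, carried by Fcgr3, of 1.44.

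The remaining lists of T cell function did not pass by camera. Cytotoxicity genes had 7 of 10 positive (median 0.29, adjusted p = 0.618), with the granzyme Gzmb at 0.36 and the granzyme inhibitor Serpinb9 at -0.60. Naive and memory genes had 8 of 18 positive (median -0.05), with the trafficking regulator Klf2 at 0.54. The IRF family had 5 of 9 positive (median 0.04), with Irf8 at 0.33 and Irf3 at 0.25, and T cell receptor and lineage genes 8 of 15 (median 0.00), with Zap70 at 0.29 and Cd247 at 0.27. Heat shock genes had 8 of 16 positive, with Gadd45g at 0.39 and Mt1 at -0.41. Cholesterol synthesis genes had 11 of 24 positive, with a median of -0.02 and a mean of 0.03, Mvd at 0.42 and Msmo1 at -0.41. Unfolded protein response genes had a median of 0.02 and a mean of -0.03, with Atf6 at -0.41 and Hsp90b1 at -0.29. Neighbours of Batf3 that missed the threshold, picked after their values were seen, included the kinase gene Cdc42bpa at 1.36 (adjusted p = 0.0682, edgeR), which passed with the GC correction, the transcription factor Usf1 at 0.68, Arhgap30 at 0.61 and the SLAM receptor Ly9 at -0.40.

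After called genes within 1 Mb were merged, 3 of 11 loci lay within 25 Mb of Batf3 (permutation p = 4.6e-04, 100000 draws). This test and its window were chosen after the results were seen, and the draws do not allow for that choice. With that limit, the clustering argues against loss of BATF3 acting on genes wherever they lie as the whole account. Of the 7 called neighbours, 0 lay within 2 Mb, and 1 of 24 tested genes there had an unadjusted p under 0.05 in edgeR. With so few genes and a 2 Mb limit also set afterwards, this cannot decide whether a disturbance spread from the targeted allele to its immediate neighbours. Myeloid cells in the knockout cultures, as a source of Fcgr3, were not seen: the median log2 ratio of Lyz2, Cst3, Tyrobp, Fcer1g, Ctss and Csf1r was 0, with Lyz2, Tyrobp and Fcer1g at 0 counts in all libraries and Cst3 at 46.0 to 53.3 CPM. Reads shared between Fcgr3 and Fcgr2b could account for the Fcgr2b signal, as their fractional counts added up to whole reads in the 2 Batf3-/- libraries, while the sum of the pair, 4 and 9 in WT and 604 and 240 in Batf3-/- libraries, does not depend on how they divide. A candidate explanation that stays open is a segment of other-strain DNA around the targeted locus, retained from the cells in which the allele was made: of the genes near Batf3 that were not called, 13.0% had an unadjusted p under 0.05 against 4.55% elsewhere (Fisher's exact p = 6.96e-05). That excess lay in the stretch from 170 to 180 Mb (15 of 59 genes) and not in the rest of the window (3 of 79, or 3.80%), the labels name no strain, and effects of BATF3 on Slamf7 or Uap1 themselves remain possible.

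The split in sex-linked RNA between replicates 1 and 2 may reflect cells of both sexes in the replicate 2 libraries of both genotypes. There Xist was high while each of the 4 Y-linked genes lay below its replicate 1 level of the same genotype, at 38.4% to 49.3% in WT and 65.5% to 89.2% in Batf3-/- cells. Cross-assignment of a small share of reads between libraries is argued against by the Xist level, which was 113% of the summed Y-linked level in WT replicate 2 and 79.1% in Batf3-/- replicate 2. The replicate 1 base of the Y-linked percentages itself differed, with summed levels of 344 CPM in WT and 243 CPM in Batf3-/- cells. Those percentages therefore do not compare the share of female cells between genotypes. The labels give no sex, and no biological explanation by genotype was tested.

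The upward shift of early T cell receptor genes may rest on WT replicate 1 alone. Without that library the list's median log2 fold change fell from 0.23 (quartiles 0.12 to 0.36) to 0.06 (quartiles -0.14 to 0.21), or 27.9% of its value, and 12 of 20 members rather than 19 were positive. The GC content of the transcripts cannot be told apart from this: the list's median GC was 54.0% against 49.8% for all tested genes, and the deviations of WT replicate 1 fell with GC (Spearman's rho across genes -0.56) while those of the Batf3-/- replicates rose (0.35 and 0.43). After the GC correction 45.3% of the median was kept (0.10, quartiles 0.05 to 0.28; adjusted p = 0.0827, limma's camera), with 16 of 20 members positive; the median was lower and the p higher than before, with the unadjusted p still under 0.05. An effect of genotype on these genes remains open and was not tested apart from the libraries.

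The 4 libraries can be split into 2 and 2 in only 3 ways. The genotype split, which called 16 genes, was the 1 split of the 3 with that many, and the highest of the others, by replicate number, called 3. At an unadjusted p under 0.05 the order was the other way in edgeR, with 583 genes by genotype, 864 by replicate number and 296 in the crossed split. Of the 16 genes 8 were Batf3 and its neighbours. With 3 splits no share under 0.05 can be reached.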
